A study of Homo sapiens with 6 samples.

How the data were processed

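Bulk RNA-seq was deposited for 6 libraries of human cells labelled CCRF-SB, a line established from the blood of a patient with B cell acute lymphoblastic leukaemia. 3 libraries, called siControl here, came from cells given an empty lentiviral vector, and 3, called siANXA1, from cells given a lentiviral vector that silences ANXA1. Cells were selected with puromycin and collected on day 5, and total RNA was made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The groups and the replicate numbers 1 to 3 were taken from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

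The authors deposited estimated counts per transcript, rounded to whole numbers and not normalized, as a table with annotation and a table without. All 1335690 values were equal in both. That the values are estimated counts and not tallied reads was read from the values: several mitochondrial transcripts held the same few counts in nearly every library, and overlapping transcripts of a gene each had their own share. The aligner, assembler, counting tool and strand setting are not given in the sources used here. The only genome build named, per the submitters' processing notes, is mm10, a mouse build, whereas all 206601 rows with an Ensembl transcript were found in GENCODE release 29 on the human build GRCh38, 206568 of them with the same start and end and all with the same gene. Coordinates below are those of GRCh38 from the deposited annotation. A further 16014 rows, named TCONS_, carried no gene or position. They held between 16.9% and 17.7% of each library's counts and stayed out of the gene tests and library sizes. Transcript lengths in the table were read but entered no test.

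Counts were summed per gene over its transcripts, which gave 58735 genes, 34795 of them with a count. Totals with a gene ranged from 21333951 in siANXA1 replicate 2 to 44148505 in siANXA1 replicate 1. Reads of near-identical genes, overlapping genes and antisense genes may be divided arbitrarily by such estimates, which the tests do not see. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, robust glmQLFit, glmQLFTest), with group as the only term, and Benjamini-Hochberg adjustment over all genes tested. An adjusted p under 0.05 was the threshold throughout, and all tests were two-sided. Levels are CPM, the usual count relative to library size, scaled by TMM and given as mean ± SD over 3 libraries. Levels of lineage genes, many of which did not pass the filter, are CPM without TMM.

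Before the data were examined, 37 gene lists were fixed, covering annexins, growth, survival and drug handling, stress responses, B cell identity, RNA quality and markers of other cell types. Of their 947 entries, 944 matched a gene. Lists with 5 or more tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at an inter-gene correlation of 0.01, with camera at an estimated correlation and fry as alternatives. With an estimated correlation, camera takes its degrees of freedom from the residuals of the 6 libraries, so it has little power here. GO and KEGG terms from the deposited annotation with 15 to 300 tested genes were tested in the same way. Transcripts were tested with the same edgeR model, and transcript usage with diffSpliceDGE. The rule for named genes, also fixed beforehand, took ANXA1, up to 12 protein coding genes per direction with the largest change among those past the threshold with a mean of 5 CPM or more and groups that did not overlap, up to 4 members of each list past the threshold at 1 CPM or more or otherwise its 2 members with the highest mean CPM, and all tested annexins, S100 proteins and annexin A1 receptors. Other genes named below were chosen after their values were seen, and this is said where they appear.

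The test of all genes was checked on simulated counts with the means, library sizes and spread of siANXA1 against siControl over 17947 genes. It recovered 3 of 67 genes changed 2-fold, 36 of 67 changed 4-fold and 57 of 66 changed 8-fold, with 6 false calls. The transcript test, over 58702 transcripts, recovered 0 of 200 changed 8-fold with 0 false calls, and the usage test found 10 of them with 67 false calls, so single usage calls are not reliable at this spread.

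Alternatives fixed beforehand were 3 other scalings, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (10 counts in 3 libraries and a mean of 5 CPM), stricter thresholds, the most abundant transcript per gene, protein coding genes alone, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were a covariate for the 2 sides of the libraries on principal component 1, a surrogate variable from sva 3.50.0, DESeq2 with that covariate, the TCONS_ rows tested with the genes, and counts thinned to the smallest library. Figures were drawn with matplotlib 3.10.9. No library was left out, and no pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 76.9 or more).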

Results

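The data were estimated transcript counts from 6 RNA-seq libraries of cells labelled CCRF-SB, with 3 siControl and 3 siANXA1 libraries collected on day 5. Total counts were 49778490, 48174350 and 41913392 in siControl replicates 1 to 3, and 53661293, 25657804 and 45039967 in siANXA1 replicates 1 to 3. The series title names proliferation and drug resistance as the processes for which ANXA1 was studied.

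ANXA1, which encodes a calcium-dependent phospholipid-binding protein of the annexin family, was lower in every siANXA1 library than in every siControl library. Its gene lies on chromosome 9 from 73151757 to 73170393, on the plus strand (GRCh38). The level was 3716 ± 34.3 CPM (SD, n = 3) in siControl and 1680 ± 64.3 CPM (SD, n = 3) in siANXA1, so that 45.2% remained. The libraries read 3696, 3696 and 3756 CPM against 1606, 1723 and 1712 CPM. The log2 fold change was -1.14 ± 0.093 (SE), and edgeR's quasi-likelihood test gave an adjusted p of 0.057, just outside the threshold; DESeq2 gave an adjusted p of 3.21e-07. The exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Most of the difference lay in the coding transcript ENST00000257497, at 2916 ± 80.1 CPM in siControl and 938 ± 161 CPM in siANXA1, although the single transcript did not pass the edgeR test (adjusted p = 0.181). The coding transcript ENST00000376911 stood at 181 ± 1.90 and 169 ± 75.1 CPM.

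**Figure D1:**
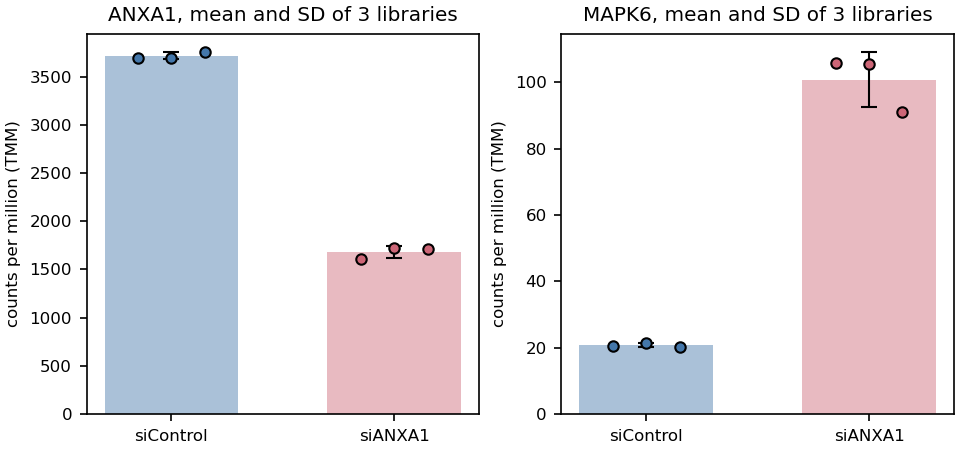
ANXA1 and MAPK6 levels in CPM scaled by TMM (y axis, from 0) in siControl and siANXA1; points are libraries, bars the mean of 3 and error bars the SD. ANXA1 stood at 3716 CPM in siControl and 1680 CPM in siANXA1, and MAPK6 at 20.8 and 101 CPM, with no overlap between the groups for either gene.

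MAPK6, which encodes the atypical MAP kinase ERK3, rose from 20.8 ± 0.593 CPM to 101 ± 8.37 CPM (SD, n = 3), a log2 fold change of 2.28 ± 0.15 (SE; edgeR adjusted p = 0.026). The gene lies on chromosome 15 from 51952106 to 52067372, on the plus strand, and has pseudogene copies that can share its reads. Most of the difference lay in its coding transcript ENST00000261845, at 20.5 ± 1.16 and 98.2 ± 7.84 CPM, although the single transcript did not pass the edgeR test (adjusted p = 0.181). The mitochondrial alanine tRNA gene MT-TA, named after its values were seen because the rule took protein coding genes, stood at 0.594 ± 0.306 and 75.5 ± 7.40 CPM (edgeR adjusted p = 0.026). It is 69 bases long, and estimated counts of so short a transcript are uncertain. These were the only 2 of 17947 genes past the threshold, and both rose. 0 genes fell, against 1423 genes at an unadjusted p under 0.05 (611 higher, 812 lower), and DESeq2 called 69 genes higher and 91 lower while limma-voom called 2 and 1. In 2629 genes (14.6%) the groups did not overlap, where chance gives 10%. MAPK6 kept its direction without each library in turn, with log2 fold changes from 2.24 to 2.35, but its adjusted p passed 0.05 without siControl replicate 1 (0.18), siControl replicate 2 (0.128), siANXA1 replicate 1 (0.119), siANXA1 replicate 2 (0.0791) or siANXA1 replicate 3 (0.142), and reached 0.0487 without siControl replicate 3. With the most abundant transcript per gene, its call also ended (edgeR adjusted p = 0.0662), as it did with the replicate number as a block (edgeR adjusted p = 0.334). The count of called genes was 0 without siControl replicate 2 or any 1 of the siANXA1 replicates, and 7 without siControl replicate 3.

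Among genes next in rank, all named after their values were seen, ID3, an inhibitor of basic helix-loop-helix transcription factors, stood at 52.4 ± 5.24 CPM in siControl and 14.8 ± 1.67 CPM in siANXA1. UBA6, a ubiquitin-activating enzyme, stood at 81.1 ± 11.2 and 15.3 ± 4.47 CPM. UBR2, a ubiquitin ligase, stood at 32.5 ± 6.29 and 129 ± 14.7 CPM, the sialyltransferase gene ST6GAL1 at 48.2 ± 0.330 and 155 ± 33.2 CPM, and TMSB10, an actin-monomer-binding thymosin, at 162 ± 16.2 and 417 ± 62.4 CPM. None passed edgeR (adjusted p from 0.122 for ID3 and UBR2 to 0.142 for the others), and the 3 libraries of each group did not overlap for any of them. In DESeq2, ID3 and UBR2 passed with adjusted p of 4.83e-11 and 2.3e-10, UBA6 with 2.64e-11, ST6GAL1 with 3.21e-07 and TMSB10 with 9.92e-06. TMSB10 also passed edgeR with the sides of the first principal component, described next, as a covariate chosen after seeing the data (adjusted p = 0.0201).

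The spread between libraries was large, with a common biological coefficient of variation of 0.423. The first principal component, with 39.9% of the variance, placed siControl replicates 1 and 2 with siANXA1 replicate 2, and siControl replicate 3 with siANXA1 replicates 1 and 3, so it crossed the groups. DDIT4, a stress-induced inhibitor of mTOR signalling, read 2282, 2171 and 189 CPM in siControl replicates 1 to 3 and 110, 1435 and 109 CPM in siANXA1 replicates 1 to 3. PHGDH, the first enzyme of serine synthesis, named after its values were seen, read 107, 98.2 and 8.86 CPM and 4.30, 33.0 and 4.20 CPM in the same order. On the second principal component, with 23.3% of the variance, the groups did not overlap. It placed siControl replicates 1 to 3 at 41.9, 33.8 and 22.0 and siANXA1 replicates 1 to 3 at 0.011, -89.9 and -7.84. Most of that range came from siANXA1 replicate 2, the library with the fewest counts.

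Of the other annexins, none of the 8 tested passed the threshold. ANXA2 stood at 239 ± 10.9 CPM in siControl and 289 ± 19.2 CPM in siANXA1, ANXA11 at 252 ± 54.0 and 195 ± 29.995 CPM, and ANXA7 at 246 ± 39.7 and 271 ± 18.4 CPM. ANXA5 stood at 146 ± 17.7 and 156 ± 33.8 CPM, ANXA4 at 17.3 ± 3.51 and 19.965 ± 4.66 CPM and ANXA6 at 16.5 ± 11.4 and 16.2 ± 11.9 CPM. ANXA3 stood at 6.73 ± 4.79 and 1.72 ± 0.310 CPM and ANXA9 at 1.76 ± 2.32 and 1.23 ± 1.26 CPM. Adjusted over the list alone, 1 of the 9 tested family members passed, ANXA1 itself, and over all genes 0 did. Of the S100 proteins, calcium-binding partners of annexins, S100A11 stood at 136 ± 29.001 and 88.2 ± 5.83 CPM (edgeR adjusted p = 0.605), and S100A6 at 46.7 ± 3.03 and 41.4 ± 5.94 CPM. S100A13 stood at 21.7 ± 7.18 and 28.3 ± 10.8 CPM, S100A4 at 15.7 ± 3.23 and 11.1 ± 4.67 CPM, S100A16 at 11.7 ± 5.55 and 7.16 ± 4.92 CPM, and S100A10 and S100A2 averaged 4.80 and 0.292 CPM over all libraries. The formyl peptide receptor genes FPR1 and FPR3 averaged 0.539 and 3.68 CPM.

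Of the 37 gene lists, camera called 4 lower and 3 higher in siANXA1. In the composition of the RNA, the shares of mitochondrial rRNA and of the 10 most abundant genes also differed between the groups without overlap. The shares of mitochondrial mRNA, protein coding genes and TCONS_ rows overlapped. Mitochondrial rRNA held 2.10%, 2.15% and 1.15% of the counts with a gene in siControl replicates 1 to 3 and 0.808%, 1.09% and 0.787% in siANXA1 replicates 1 to 3. The 10 most abundant genes held 9.87%, 9.90% and 8.09% against 7.85%, 7.30% and 7.74%. These shares are not separate, since the mitochondrial rRNA gene MT-RNR2 (815765 counts in siControl replicate 1) enters both. MT-ND4 had 958 counts in siANXA1 replicate 2 and between 374260 and 713670 elsewhere. That lowers the 7.30% of siANXA1 replicate 2, so its lack of overlap may rest on an unstable estimate. The smallest adjusted p was that of targets of ATF4, the transcription factor of the amino acid response, of which 26 of 27 tested members had a negative fold change, with a median log2 fold change of -0.97 (limma camera adjusted p = 3.07e-05; adjusted p = 0.856 with an estimated correlation). Among its members, DDIT4 and the amino acid transporter gene SLC7A5 (541 ± 129 and 448 ± 132 CPM) were the most abundant, and TRIB3 and ASNS, named after their values were seen, stood at 272 and 88.4 CPM and at 577 and 264 CPM. The median deviation of the list was 1.38, 1.33 and -0.77 in siControl replicates 1 to 3 and -1.17, 0.56 and -0.85 in siANXA1 replicates 1 to 3, the same division as on the first principal component. DDIT4 is among the genes with the largest loadings on that component, so this likeness was partly built in and is no separate evidence. Within the side of that component holding siControl replicates 1 and 2 and siANXA1 replicate 2 the median difference of log2 CPM was -0.63, and within the other side it was -0.18.

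Immediate early genes and MAPK feedback genes, transcribed within minutes of growth factor signalling, were lower as a list, with 18 of 24 members negative and a median of -0.50 (camera adjusted p = 5.73e-05; adjusted p = 0.856 with an estimated correlation). EGR1 stood at 334 ± 110 and 145 ± 83.1 CPM and IER2 at 72.1 ± 52.4 and 111 ± 121 CPM. Adjusted over the list alone, 2 members passed, both lower. Interferon-stimulated genes were also lower, with 21 of 27 negative and a median of -0.43 (adjusted p = 0.00107; adjusted p = 0.64 with an estimated correlation). IFITM1, a membrane protein that restricts virus entry, stood at 341 ± 42.9 and 223 ± 6.81 CPM and BST2 at 164 ± 3.36 and 152 ± 5.68 CPM. NF-kB targets had 15 of 20 members negative (adjusted p = 0.0443; adjusted p = 0.856 with an estimated correlation), with TNIP1 at 60.5 ± 10.2 and 40.7 ± 13.5 CPM and RELA at 63.6 ± 12.96 and 69.3 ± 5.71 CPM.

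Erythroid and megakaryocyte genes were higher as a list, with 11 of 14 positive and a median of 0.65 (camera adjusted p = 0.00638; adjusted p = 0.856 with an estimated correlation). The fetal globin genes HBG2 and HBG1, near-identical copies whose reads can be exchanged, stood at 360 ± 149 and 829 ± 56.5 CPM and at 133 ± 68.7 and 492 ± 340 CPM, and HBG2 passed edgeR without siControl replicate 3 (adjusted p = 0.0487). Replication-dependent histones had 12 of 16 positive and a median of 0.42 (adjusted p = 0.0228; adjusted p = 0.64 with an estimated correlation), with the linker histone gene HIST1H1C at 1018 ± 99.2 and 1380 ± 172 CPM and HIST1H2AC at 129 ± 13.7 and 207 ± 44.6 CPM. Histone genes are also near-identical to one another. MYC targets and ribosome biogenesis genes had 28 of 32 positive and a median of 0.31 (adjusted p = 0.0429; adjusted p = 0.863 with an estimated correlation), although NPM1 stood at 1987 ± 486 and 1148 ± 529 CPM and HSPD1 at 1201 ± 358 and 1353 ± 277 CPM. MYC itself, named after its values were seen, was lower in DESeq2 (log2 fold change -2.58, adjusted p = 0.0217) and did not pass edgeR (adjusted p = 0.605). DESeq2 with the sides of the first principal component as a covariate gave MYC an adjusted p of 0.221. The estimated correlation was 0.88 for the ATF4, 0.64 for the MYC, 0.34 for the immediate early and 0.33 for the erythroid list. It was 0.037 for the interferon and 0.023 for the NF-kB list, and -0.041, below the preset 0.01, for the histone list. For the histone list a high correlation therefore does not account for the lost call. Over all genes 0 members of these 7 lists passed the edgeR threshold. With the sides of the first principal component as a covariate, chosen after seeing the data, camera gave an adjusted p of 4.86e-05 for the ATF4 list at the preset correlation and an adjusted p of 0.702 with an estimated correlation, and the erythroid (0.0713), NF-kB (0.0569) and MYC (0.816) lists no longer passed at the preset correlation. The MYC list also lost its call without siControl replicate 1 (0.456), siControl replicate 2 (0.512), siANXA1 replicate 1 (0.308) or siANXA1 replicate 3 (0.25). The histone list lost its call without siControl replicate 2 (0.0531), siControl replicate 3 (0.0621) or siANXA1 replicate 2 (0.107), and the NF-kB list lost it without siControl replicate 1 (0.247), siControl replicate 2 (0.0832), siANXA1 replicate 1 (0.123) or siANXA1 replicate 2 (0.057). Among the planned settings, the strict filter ended the calls of the histone (0.168) and MYC (0.0551) lists, DESeq2 that of the MYC list (0.0965), and no filter (0.194) and upper quartile scaling (0.0542) that of the NF-kB list.

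**Figure D2:**
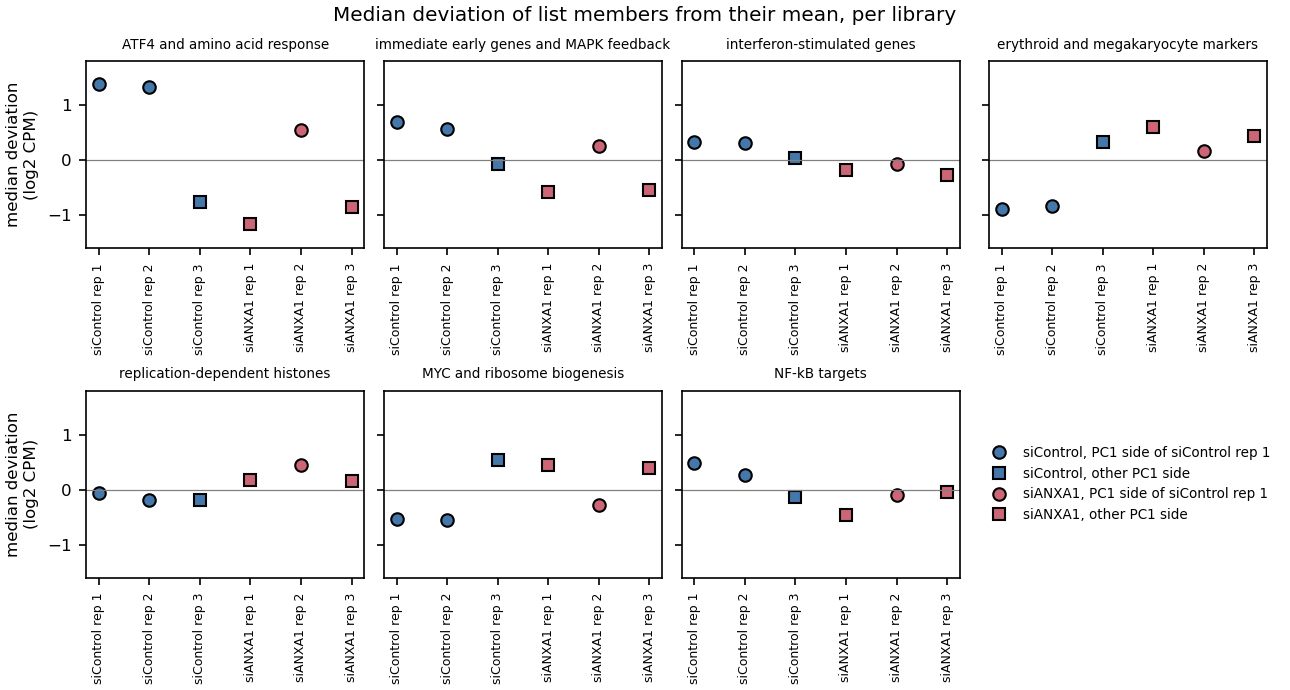
Median deviation of list members from their own mean over the 6 libraries (y axis, log2 CPM) in each library (x axis), for the 7 lists camera called; colour gives the group and the marker shape the side on the first principal component. The ATF4 list read 1.38 and 1.33 in siControl replicates 1 and 2 and -0.77 in siControl replicate 3, against 0.56 in siANXA1 replicate 2.

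Of the lists tied to the processes in the series title, those that follow did not pass with all 6 libraries and group as the only term. The histone, MYC and immediate early lists above, which also bear on growth, passed at the preset correlation. G1/S and DNA replication genes had 26 of 36 positive (camera adjusted p = 0.296) and were called higher without siControl replicate 3 (adjusted p = 0.0098). That fit leaves siControl replicates 1 and 2, which lie on the same side of the first principal component. With the side as covariate, chosen after seeing the data, the list was not called (camera adjusted p = 0.996, lower). MCM7 stood at 573 ± 78.5 and 581 ± 34.9 CPM and MCM4 at 478 ± 181 and 523 ± 29.4 CPM. G2/M genes had 16 of 32 positive (adjusted p = 0.566), with TOP2A, the target of etoposide and doxorubicin, at 967 ± 41.3 and 893 ± 38.3 CPM and TPX2 at 458 ± 23.3 and 383 ± 7.55 CPM. CDK inhibitors and cell cycle brakes (0.726), p53 targets (0.16, and 0.0477, lower, with the surrogate variable, chosen after seeing the data), BCL2 family and apoptosis genes (0.977) and PI3K and mTOR components (0.625) gave the camera adjusted p in brackets. CDKN2C stood at 128 ± 13.2 and 98.7 ± 8.45 CPM, MCL1, an inhibitor of apoptosis, at 668 ± 96.2 and 544 ± 83.0 CPM, and SESN2, a stress-induced p53 target, at 257 ± 150 and 131 ± 127 CPM. Drug efflux and drug handling genes had 19 of 34 positive (0.854), with GSTP1, a glutathione transferase, at 641 ± 56.5 and 656 ± 28.4 CPM. Glucocorticoid response genes gave 0.566, with TXNIP at 768 ± 255 and 463 ± 117 CPM. In the simulation at this spread, 3 of 67 single genes changed 2-fold were recovered, so differences of that size in single genes were mostly not detectable, whereas camera called 3 of 3 lists whose members, drawn independently, were all raised 2-fold, and 1 other list.

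Heat shock genes gave an adjusted p of 0.141, the unfolded protein response 0.296, glycolysis and hypoxia 0.916, nuclear oxidative phosphorylation 0.296, mitochondrially encoded genes 0.25, cytosolic ribosomal proteins 0.296, cholesterol synthesis 0.296, DNA repair 0.671, adhesion and migration 0.343, the actin cytoskeleton 0.854, cytokines and chemokines 0.232, MHC class I 0.296, the annexin family 0.53 and S100 proteins with annexin A1 receptors 0.296 (camera in limma). Without siControl replicate 3, heat shock genes were called higher (0.0098) and cytokines and chemokines lower (0.0255). Neither list was called by camera with the principal component side as covariate (0.332 and 0.873). The endoplasmic reticulum chaperone genes HSP90B1 and CALR stood at 2381 ± 656 and 3593 ± 219 CPM and at 1700 ± 527 and 2760 ± 320 CPM. GAPDH stood at 4232 ± 124 and 4325 ± 25.4 CPM. VIM, an intermediate filament gene, stood at 2481 ± 943 and 1404 ± 337 CPM. The actin list was called in direction as lower though its median (0.01) and mean (0.09) were positive, and B precursor genes as higher though their mean was -0.13.

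Genes that mark B cells were low in all 6 libraries. CD79A, a chain of the B cell receptor complex, read between 0.054 and 0.703 CPM, and CD74, the MHC class II invariant chain, between 0.204 and 0.927 CPM, while the immunoglobulin genes IGHM and IGKC had 0 counts in every library. Of the 42 genes in the lists of B cell identity and MHC class II presentation, 10 reached a mean of 5 CPM, among them LYN and IKZF1, which other blood cells also express. In contrast, 12 of the 18 erythroid and megakaryocyte genes reached 5 CPM, with GATA1, the erythroid transcription factor, between 133 and 196 CPM, and HBG2 between 277 and 870 CPM. KRT8, an epithelial keratin, read between 193 and 301 CPM. The lists for B cell identity (camera adjusted p = 0.6), B precursors (0.726), plasma cells (0.165), MHC class II (0.589), T and NK cells (0.203), myeloid cells (0.165), fibroblast, endothelial and epithelial cells (0.6) and the kidney packaging line (0.863) did not pass between the groups with all 6 libraries and group as the only term in camera. The myeloid list was called lower by camera without siControl replicate 3 (0.0255) and with the replicate number as a block (0.03). It was not called with the principal component side as covariate (0.673). The T and NK cell list passed fry for change in either direction (adjusted p = 0.00135). CTSS, a lysosomal protease of the MHC class II list, stood at 15.3 ± 4.22 and 5.61 ± 0.745 CPM, which did not pass edgeR (adjusted p = 0.574) and passed DESeq2 (adjusted p = 0.00467).

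**Figure D3:**
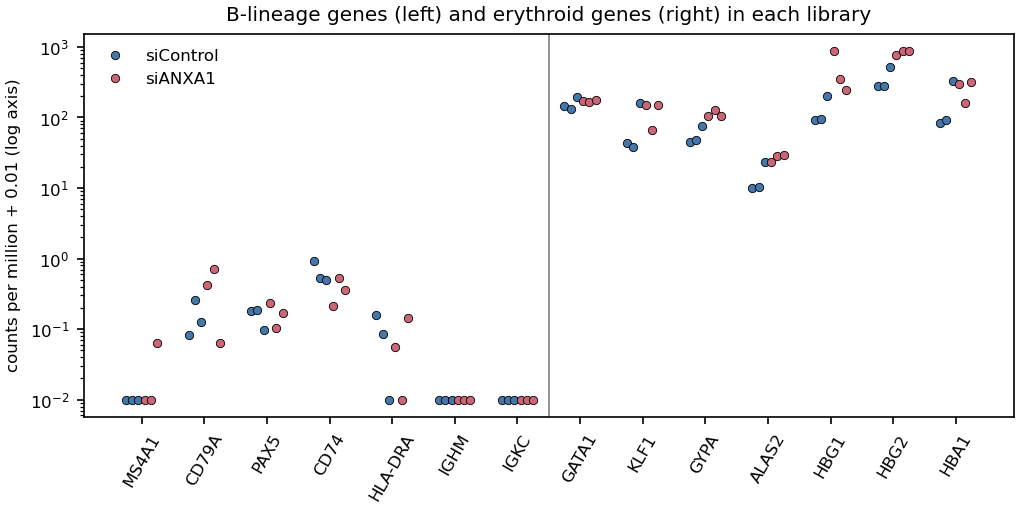
Levels of 7 B-lineage genes (left of the line) and 7 erythroid genes (right) in each library, as CPM plus 0.01 on a log axis; each point is a library, coloured by group. CD74 stayed at or below 0.927 CPM and GATA1 at or above 133 CPM in all 6 libraries.

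Of 58702 transcripts tested, 1 passed edgeR, lower, and 0 rose (2756 at an unadjusted p under 0.05). It was ENST00000567188 of CNOT1, a scaffold of the deadenylase complex, annotated as subject to nonsense-mediated decay, at 375 ± 14.7 CPM in siControl and 0.144 ± 0.0495 CPM in siANXA1 (adjusted p = 0.00642), while CNOT1 summed over its transcripts stood at 522 and 437 CPM (adjusted p = 0.645). Without siControl replicate 1 or 3, or siANXA1 replicate 1 or 3, 0 transcripts passed, and without siControl replicate 2 the 1 that passed was higher. Transcript usage was called in 124 of 10224 genes, led by CNOT1 and HNRNPU, an RNA-binding protein of the nuclear matrix. ENST00000640056 of HNRNPU stood at 465 ± 114 CPM in siControl and had no counts in siANXA1, and ENST00000366525 stood at 2.48 ± 0.775 and 332 ± 184 CPM. In simulated data with this spread most usage calls were false.

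Of 2399 GO and KEGG terms, camera called 5 higher and 4 lower. The highest ranked were DNA-directed RNA polymerase activity, with 33 of 40 genes positive (adjusted p = 0.0123), collagen catabolic process, with 30 of 36 negative (adjusted p = 0.0123), methylosome, with 18 of 19 positive (adjusted p = 0.0131), and nucleosome, with 49 of 67 positive (adjusted p = 0.0131). With an estimated correlation, adjusted p = 0.977 for each of them, and 0 terms were called. With the principal component sides as covariate, nucleosome alone was called (adjusted p = 0.0028).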

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

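The rows named TCONS_, which carry no gene and entered none of the comparisons above, held a difference between the groups. When they were tested with the genes, a choice made after seeing the data, 1 of 12438 such rows was higher in siANXA1 than in siControl at an adjusted p under 0.05 in edgeR, and 2 were lower. The higher row, TCONS_00143778, read 8.61, 8.58 and 11.5 CPM in siControl and 163, 136 and 180 CPM in siANXA1 (adjusted p = 0.0477). The lower rows TCONS_00175362 and TCONS_00012589 read 50.05, 45.2 and 61.8 CPM against 0.931, 1.27 and 0.678 CPM, and 71.5, 81.1 and 85.3 CPM against no counts. At an unadjusted p under 0.05, 6.52% of these rows differed, a smaller share than the 7.93% of genes in the main edgeR test. No biological explanation was tested, since the rows name no gene.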

How the results depend on the processing

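Tests with the principal component side, the surrogate variable, the thinned counts and the TCONS_ rows were chosen after seeing the data. ANXA1 summed over its transcripts was lower under every alternative run, with log2 fold changes from -1.16 to -1.11 when libraries were left out and adjusted p from 1.76e-26 to 0.392. Of its 8 transcripts tested alone, the noncoding ENST00000489109 (0.49) and ENST00000491192 (0.24) went the other way, and none of the 8 passed (adjusted p from 0.181 to 0.998). It passed the threshold with the strict filter (-1.17), limma-voom (-1.15), DESeq2 (-1.15), DESeq2 with the side (-1.15), the side (-1.14) or surrogate variable (-1.14) in edgeR, thinned counts (-1.15), TCONS_ rows (-1.17) and without siControl replicate 3. The 2 called genes became 160 with DESeq2, 839 with DESeq2 and the side, 5 with the side in edgeR and 9 with the surrogate variable. With TCONS_ rows tested too, 5 rows were called, among them 1 TCONS_ row higher and 2 lower. The genes called there were MAPK6, alone of the 2, and ANXA1. The 2 called genes became 1, MAPK6, for protein coding genes and 0 at an adjusted p of 0.01 in edgeR. With the most abundant transcript per gene neither stayed called (MAPK6 adjusted p = 0.0662) while 1 other gene was, lower. Leaving out libraries gave 0 to 7 genes in edgeR, and moved the 1423 genes at an unadjusted p under 0.05 to between 721 without siControl replicate 1 and 3701 without siControl replicate 3 (774 without siControl replicate 2, and 906, 2127 and 905 without siANXA1 replicates 1 to 3). Both genes stayed called under all 3 other scalings, no filter, the strict filter, both covariates and DESeq2. No filter, the strict filter and limma-voom each gave 2 higher and 1 lower, DESeq2 69 and 91, and none of the scalings moved the share of higher calls. The called lists, 7 in the main test, numbered 4 to 10 without single libraries, 4 with the side, 0 with an estimated correlation, 0 with fry for a shared direction and 3 with fry for change in either direction, none of the 3 being among the 7: the actin cytoskeleton (adjusted p = 1e-04), T and NK cells (0.00135) and nuclear oxidative phosphorylation (0.0397). Called transcripts, 1 in the main test, numbered 0 to 1 without single libraries. Usage genes, 124 in the main test, numbered 21 with the strict filter and 131 to 370 without single libraries. Terms, 9 in the main test, numbered 0 with an estimated correlation and 1 with the side. With the replicate number as a block (replicate block), genes numbered 0 (1475 at an unadjusted p under 0.05), transcripts 0, usage genes 65, lists 8 and terms 6; MAPK6 then had a log2 fold change of 2.27 and an adjusted p of 0.334, and the list gained was that of myeloid markers, lower (0.03). Whether the numbers pair the libraries stays open. Same-numbered libraries had deviation correlations of -0.114, 0.263 and 0.256. Among the siANXA1 libraries, siControl replicates 2 and 3 each correlated best with the library of their own number. For siControl replicate 3 the value with siANXA1 replicate 1 was close (0.21). In contrast, siControl replicate 1 correlated best with siANXA1 replicate 2 (0.226). Apart from fewer samples or genes tested, the cause of these changes was not tested. Depth limited siANXA1 replicate 2 the most, with 25657804 counts, but thinning every library to its total gave 3 genes.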

Other observations

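Tests of the lineage, the split of the libraries and the spread were partly chosen after the results were seen: those of another lineage, of mixed cells, of the split for all lists and of the coefficient of variation, the count of genes under other groupings, and the counts of transcripts without counts in 3 libraries. The others in this part were written down first.

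Mitochondrial transcripts showed how single estimates can move. MT-ND4 had 958 counts in siANXA1 replicate 2 and between 374260 and 713670 in the other libraries. MT-CO3 had 44215 counts in siControl replicate 1 and 4 or 5 in the others, and MT-TC had 1 count in siANXA1 replicate 3 and between 1871 and 6431 elsewhere. The nuclear genes CYCS, which encodes cytochrome c, and LYN, a Src-family kinase, behaved alike in siControl replicate 1, where they read 22.6 and 47.2 CPM against 342 and 250 CPM in siControl replicate 2.

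The first pattern is the lack of B-lineage transcripts in libraries labelled as a B cell line, with erythroid genes high in all 6. A small share of erythroid cells among B lymphoblasts is argued against, since CD74 and HLA-DRA, abundant in such cells, reached at most 0.927 CPM in any library. A loss of genes in counting whatever their lineage is argued against too, because the share of genes under 5 CPM was 71.1 percentage points higher in the B-lineage lists (76.2% of 42 genes) than in DNA repair, cell cycle and PI3K lists (5.08% of 118 genes; Fisher's exact p = 5.4e-19, two-sided, over genes, which are not independent). For cells of another lineage the share could not decide, as 23.8% of the B-lineage genes reached 5 CPM, just over the bound of 20%. That bound was set after the values were seen, and the genes past 5 CPM included LYN and IKZF1, which other blood cells also express. MS4A1, CD79A and PAX5 read at most 0.054, 0.703 and 0.227 CPM in any library, and IGHM and IGKC had 0 counts. GATA1 read at least 133 CPM in each. For these genes the levels argue against B lymphoblasts as the main cells, and what the cells are was not tested. A candidate explanation is an erythroleukaemia line such as K562, which has lost the 9p21 region. CDKN2A, CDKN2B and MTAP, which lie there, reached at most 0.634 CPM in any library, as that hypothesis predicted. Other lines with this loss were not compared, and whether the labelled line carries it was not tested, so these values do not single out K562.

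The second pattern is the set of called gene lists, beside the division of the libraries on the first principal component. For the ATF4 list at the preset correlation, a lower depth of siANXA1 replicate 2 is argued against by thinning, after which the camera adjusted p was 2.04e-05. Leaving that library out (7.88e-08) could not decide. The list was higher there (median deviation 0.56) than in siANXA1 replicates 1 and 3 (-1.17 and -0.85), so its removal could hardly end a lower call. With an estimated correlation the list was not called in the full counts either (0.856). For the MYC list the division fits: its adjusted p became 0.816 with the side as covariate, and its mean difference of log2 CPM within the sides was -0.04. Its mean edgeR log2 fold change was 0.20. For the erythroid and NF-kB lists it stays open. Their smaller adjusted p was 0.0569, and their mean differences of log2 CPM within the sides were 0.39 and -0.20. Their mean edgeR log2 fold changes were 0.49 and -0.34. The edgeR values and the differences of log2 CPM are unlike measures, so the size of any shrinkage cannot be read from them. Values within the sides are averages over both sides: the erythroid mean was 0.66 on the side of siControl replicates 1 and 2 and 0.11 on the other. The NF-kB mean was -0.29 and -0.11 in the same order. The ATF4 list had an adjusted p of 4.86e-05 with the side, but 0.702 with the side and an estimated correlation. Its mean edgeR log2 fold change was -1.15, and its mean differences of log2 CPM were -0.79 and -0.24 within the sides. The division and an effect of the knockdown therefore cannot be told apart for the ATF4 list. The histone (0.00409), interferon (0.0299) and immediate early (0.0361) lists also passed with the side. Their mean differences of log2 CPM within the sides were 0.53 and 0.20, -0.59 and -0.34, and -0.33 and -0.34. Their mean edgeR log2 fold changes were 0.37, -0.50 and -0.58 in the same order. But each had an adjusted p of 0.608 with the side and an estimated correlation, and no explanation was tested for them.

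The third pattern is the large spread between replicates with few calls. The division of the libraries is argued against as its whole source, since the common biological coefficient of variation fell only from 0.423 to 0.342 with the side as covariate. An exchange of estimated counts between transcripts of a gene fits at the transcript level: over 4325 genes the deviations of the 2 most abundant transcripts had a median correlation of -0.178 across libraries, against 0.00655 for transcripts of different genes, and the coefficient of variation of transcripts was 0.813. Such an exchange within genes leaves gene sums unaltered, so it cannot explain their spread (0.423) or the few called genes. No biological explanation was tested.

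Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, 4 gave as many genes as the real one (2 genes, highest other 2896; at an unadjusted p under 0.05, 1423 genes against 5899 in that split and 265 to 670 in the remaining ones), 3 as many transcripts (1, highest other 19), 5 as many usage genes (124, highest other 322), 2 as many lists (7, highest other 14) and 4 as many terms (9, highest other 95), the real split included each time. The highest other was in every case the split along the first principal component, which was read from the same data, so these counts restate that division of the libraries and are no separate evidence for it. Apart from it, the next highest count of lists was 6. Transcripts at 5 CPM or more in 3 libraries and without counts in the other 3 numbered 13 in the real split and 10 to 30 in the others.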
